A study of Saccharomyces cerevisiae with 22 samples.

How the data were processed

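Transcription start sites of Saccharomyces cerevisiae (W303 background) were profiled by TL-seq, which sequences the 5′ ends of polyadenylated RNA after the cap is removed with the enzyme Cap-Clip. The labels describe 22 libraries from 5 genotypes, grown in YPD and either left untreated or given 5 mM dithiothreitol (DTT) for 1 h. DTT reduces disulphide bonds and unfolds proteins in the endoplasmic reticulum (ER). The 2 wild-type strains, called SWI3 and SNF2 after the gene put back, carry a deletion complemented by the integrated wild-type gene. The 3 mutants are swi3E815X, snf2W935R and snf2Q928K, which alter the Swi3 and Snf2 subunits of the Swi/Snf chromatin remodelling complex. Each genotype and treatment has 2 replicates that, per the labels, were collected on separate days. The other 2 libraries are SWI3 controls made without Cap-Clip, 1 untreated and 1 with DTT, and enter no comparison.

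The values came from 7 comparison tables that the authors deposited, 1 for DTT against untreated wild type and 6 for a mutant against wild type under 1 of the 2 treatments. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with HISAT2 and tested with DESeq2 on sacCer3/R64; versions are not given in the sources used here. Per the file headers, each line is a consensus cluster of start sites with its mean normalized count, and a cluster is assigned to a gene by the authors. The log2 fold changes and their standard errors (SE) were computed by the authors from counts scaled by size factors, as the submitters' notes describe. The deposited Wald statistic, the score used for the gene lists, equalled the log2 fold change divided by its SE. The p-value columns were deposited by the authors, and the adjusted p was, on recalculation, a Benjamini-Hochberg adjustment over every cluster with a p. No values per library were used here, so SD, n and depth per library are unknown, as is the number of libraries that show a direction, and precision is given as the authors' SE. The sum of mean normalized counts per table was between 5901941 and 7516016, and the median SE among clusters with at least 50 mean normalized counts was between 0.35 and 0.485. The median log2 fold change of those clusters lay between -0.04 and 0.03.

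The tables were joined by cluster number, since the wild-type table has another line order. Each holds 5195 clusters, and 2 lines without values per table were not used. Each mutant table had 1 stray line outside the clusters, and 1 gene cell with a stray entry in the snf2Q928K DTT table was read as SNF11 from the other tables. Clusters were named by the symbols and coordinates of the reference annotation (R64) and classed by the position of their midpoint relative to the coding start. The clusters named 3872 genes, of which 3773 matched a reference symbol. Upstream of a coding start lay 3567 clusters, 756 were inside a coding region, 710 were intergenic, 100 were assigned to several genes and 62 to a gene outside the reference. Intergenic clusters are called here by their cluster number.

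A cluster was called higher, lower or changed at an adjusted p under 0.05. The wild-type libraries behind each table were inferred from the deposited means and fold changes, from which the mean of each arm was computed. Both snf2 mutants had the same wild-type means, with robust SDs of 0.00071 and 0.00093 log2 units between their tables. The swi3 tables had others, and the wild-type table equalled the mean of both sets. That table therefore has 4 libraries per arm, and each mutant table sets 2 mutant libraries against 2 wild-type libraries. Where a size or call is said below to depend on the wild-type set, it could change against the other set. A difference that a mutant shares with its own wild-type strain cancels in its table. No mutant was compared with both sets, so whether this held was not tested.

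The difference between a mutant's effect under DTT and untreated, and the difference between mutants under 1 treatment, was the difference of log2 fold changes. It was tested two-sided against a normal distribution with the root of the summed squared SEs, with Benjamini-Hochberg adjustment over all clusters. Between swi3E815X and a snf2 mutant, such a difference also holds the difference between their wild-type sets. Overlaps of calls were set against the number expected if the calls of each table fell independently. Covariances were set against the mean of 100 simulations of no effect that had the deposited SEs, with a shared control arm for the snf2 pair. The DTT response of each mutant was the wild-type response plus the difference of its effects, and its slope on the wild-type response was taken through 0. Calculations used python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.

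Before the data were examined, 31 gene lists were fixed from textbook knowledge. They cover ER folding, ER-associated degradation, ER translocation and glycosylation, vesicle coats and cargo receptors, inositol and phospholipid synthesis, ribosomal proteins, ribosome biogenesis, the respiratory chain and ATP synthase, the tricarboxylic acid cycle, cytosolic heat shock chaperones, and general stress and storage carbohydrate. Further lists cover sulfur amino acid synthesis, amino acid synthesis, iron uptake, oxidative stress and thiol redox, the phosphate response, hexose transport and invertase, glycolysis and fermentation, ergosterol synthesis, histones, G1/S, G2/M and daughter cell genes, and the cell wall. The rest are flocculins, MATa-specific and MATalpha-specific genes, the pheromone response, meiosis, the Swi/Snf subunits, and genes that textbooks describe as dependent on Swi/Snf. That last list was not split by whether Swi/Snf activates or represses a member, so the direction of its test has no single reading. Each gene was represented by its cluster with the highest mean normalized count in the wild-type table. The 28 lists with at least 5 measured members were tested with cameraPR (limma 3.58.1, R 4.3.3) on the Wald statistic, two-sided, with Benjamini-Hochberg adjustment over the lists within a comparison. The inter-gene correlation could not be estimated without values per library, so the preset value of 0.01 was used, with 0.05 as the alternative.

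Genes were named by a rule fixed before the data were examined. It took the 10 highest and the 10 lowest log2 fold changes per comparison among clusters with an adjusted p under 0.05 and at least 50 mean normalized counts. The cluster so taken is not the most abundant one of its gene for HIS4, ERG11, ERG3, ERG27, YCR051W, SNA3, PRY2, SRL1, ISU1, MEP3 and RPS23A, so these values describe secondary start sites. The rule also took SNF2, SWI3, HAC1, IRE1, HNT1, KAR2, LEU2, INO1, SUC2, SER3, PHO84 and NDC80, and up to 4 members with the smallest adjusted p of each list that passed. Reads of near-identical genes, such as ribosomal protein pairs, HXT, FIT, TDH, ENO and TSA genes, histone genes, PHO3 and PHO5, and the siderophore transporters, can be assigned to the wrong copy, so such names are uncertain. Where the lower arm lay under a floor of 3 normalized counts, the change is given as a bound, the mean normalized count over that floor.

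Alternatives fixed in advance were a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, a minimum of 50 mean normalized counts, a recomputed adjustment, median centring, an SE for shared controls, and, for the lists, ranks, log2 fold changes and the higher correlation. Added after the data were seen were 1 cluster per gene, only clusters upstream of a coding start, the ribosomal protein list without RPP1, which its name rule had matched although it is an RNase P subunit, and each mutant's own wild-type libraries in its DTT response. Checked on simulated data without correlation between genes, the list test recovered 99.6% of shifted lists and called 0.143% of unshifted ones. These rates do not cover lists of co-regulated genes. The test of the difference between treatments recovered 57.4% of simulated log2 differences of 2 in snf2Q928K, 48.7% in snf2W935R and 67.8% in swi3E815X. 1 of the higher clusters in untreated snf2Q928K is not reported here.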

Results

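Start-site use was compared across 22 TL-seq libraries, 20 of which were made with Cap-Clip and fall into 10 groups of 2 replicates (5 genotypes, untreated or with DTT). The authors' tables give 5195 clusters with a median width of 42 bp, and clusters upstream of a coding start lay a median of 47 bp from it. The depth per library is unknown, and every error printed is the SE of the authors' deposited table. The series asks how Swi/Snf acts where transcription from an upstream start site interferes with a downstream one during ER stress. The gene at its centre is HNT1, which encodes an adenosine monophosphoramidase of the histidine triad family.

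DTT reshaped start-site use in wild-type cells broadly, and this comparison gives the ER stress response against which the mutants were read. Genes of protein folding and secretion in the ER rose, and ribosomal protein, respiratory and sulfur amino acid genes fell. Of the clusters tested, 1751 (33.8%) changed, 856 higher and 895 lower, and 1409 of these changed at least 2-fold. In the authors' deposited table, KAR2, the ER Hsp70 chaperone, rose by a log2 fold change of 3.12 ± 0.29 (Benjamini-Hochberg adjusted p = 1.8e-24). INO1, inositol phosphate synthase, was at least 82.3-fold higher in the authors' deposited table, by a cluster inside its coding region. The other strongest increases in the authors' deposited table were in ULI1, an ER stress gene (log2 fold change 8.70 ± 0.26), and YPL162C (7.15 ± 0.49). At least 120.9-fold higher in the authors' deposited table was LSO1, and at least 80.7-fold HEM15, the ferrochelatase of haem synthesis. By the same bound, the authors' deposited table had RTA1 at least 57.8-fold, HIS4, at a cluster inside its coding region and not at its main one, at least 36.7-fold, MEP3, an ammonium permease, at least 18.6-fold and the intergenic clusters 5342 and 3179 at least 127.3-fold and 17.8-fold higher. The strongest decreases in the authors' deposited table included the hexose transporter HXT4 (log2 fold change -6.85 ± 1.13), the acid phosphatases PHO5 (-5.21 ± 0.66) and PHO3 (-4.49 ± 0.50), cytochrome c CYC1 (-5.21 ± 0.54) and the thiamine transporter THI7 (-5.16 ± 0.55). Also low in the authors' deposited table were MET1 (log2 fold change -4.69 ± 0.46) and MET5 (-4.37 ± 0.39) of sulfate assimilation, COA2 (-4.60 ± 0.69), the intergenic cluster 3519 (-4.28) and the oligopeptide transporter OPT1, which was at least 18.1-fold lower.

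Among the secretory lists in wild-type cells, 10 of 16 measured ER folding genes rose and none fell (11 adjusted over the list alone; median log2 fold change 1.49, cameraPR adjusted p = 1.11e-11). They included SIL1 (log2 fold change 4.33 ± 0.24 in the authors' deposited table), a nucleotide exchange factor of KAR2, EUG1 (3.24 ± 0.21), a disulphide isomerase, and FPR2 (2.50 ± 0.18). Of 13 genes of ER-associated degradation, 6 rose (6 adjusted over the list alone; adjusted p = 0.0109, cameraPR), with DER1 at 2.49 ± 0.27 in the authors' deposited table. For translocation and glycosylation, 14 of 27 genes rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 8.81e-05, cameraPR), and PMT3, a mannosyltransferase, was at 2.80 ± 0.22 in the authors' deposited table. For vesicle coats, 12 of 20 rose (13 adjusted over the list alone; adjusted p = 3.23e-05, cameraPR), led by SEC24 of the COPII coat at 4.67 ± 0.46 in the authors' deposited table. Stress genes also rose. In the general stress list 8 of 13 rose (8 adjusted over the list alone; adjusted p = 0.0028, cameraPR), in the iron uptake list 7 of 12 rose and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.000909), and in the thiol redox list 7 of 15 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00133). TFS1 (log2 fold change 3.07 ± 0.35), the siderophore transporter ARN2 (4.48 ± 0.43) and thioredoxin TRX2 (2.77 ± 0.21) were the leading members in the authors' deposited table.

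Growth genes fell in wild-type cells under DTT. Of 132 genes in the ribosomal protein list 129 fell (128 of 131 without RPP1, an RNase P subunit that the name rule took in), at a median log2 fold change of -1.65 (131 lower and 1 higher adjusted over the list alone; cameraPR adjusted p = 6.16e-56). Ribosome biogenesis lost 25 of 33 (26 adjusted over the list alone; cameraPR adjusted p = 4.32e-06) and the respiratory chain 25 of 35 (28 adjusted over the list alone; adjusted p = 1.12e-11). BRX1 (log2 fold change -1.92 ± 0.23) and the cytochrome oxidase gene COX5A (-3.04 ± 0.29) were examples in the authors' deposited table. Of the sulfur amino acid list 15 of 18 fell (16 adjusted over the list alone; median -2.04, cameraPR adjusted p = 2.68e-14), with methionine synthase MET6 at -4.12 ± 0.23 in the authors' deposited table. Amino acid synthesis had 11 of 29 lower (11 adjusted over the list alone; adjusted p = 0.00288, cameraPR), the phosphate response 7 of 11 (8 adjusted over the list alone; adjusted p = 0.00143), hexose transport 3 of 6 (3 adjusted over the list alone; adjusted p = 0.0129) and ergosterol synthesis 9 of 23 (9 adjusted over the list alone; adjusted p = 0.00836). Of the histone genes 9 of 10 fell (9 adjusted over the list alone; adjusted p = 2.23e-06, cameraPR), of the G2/M genes 5 of 6 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.000263) and of the daughter cell genes 12 of 14 (12 adjusted over the list alone; adjusted p = 2.79e-05). The phosphate transporter PHO84 (log2 fold change -1.12 ± 0.24), histone gene HHT1 (-2.63 ± 0.25) and the mating-type endonuclease HO (-2.28 ± 0.33) were lower in the authors' deposited table.

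The remaining 10 lists did not pass in wild-type cells. By cameraPR, the adjusted p was 0.068 for inositol and phospholipid synthesis, 0.115 for MATa-specific genes, 0.124 for the textbook Swi/Snf-dependent genes and 0.272 for glycolysis. It was 0.386 for both the tricarboxylic acid cycle and heat shock chaperones, 0.462 for the cell wall, 0.796 for G1/S, 0.856 for the pheromone response and 0.907 for the Swi/Snf subunits. Flocculins had 3 measured members and meiosis genes 1, too few to test, and MATalpha-specific genes had no cluster. HAC1, the transcription factor of the unfolded protein response, rose at the main cluster it shares with YFL032W by a log2 fold change of 0.89 in the authors' deposited table (Benjamini-Hochberg adjusted p = 0.00015). SNF2, SWI3, IRE1 and SUC2 were not called in any table, and LEU2 and NDC80 had no cluster.

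**Figure D1:**
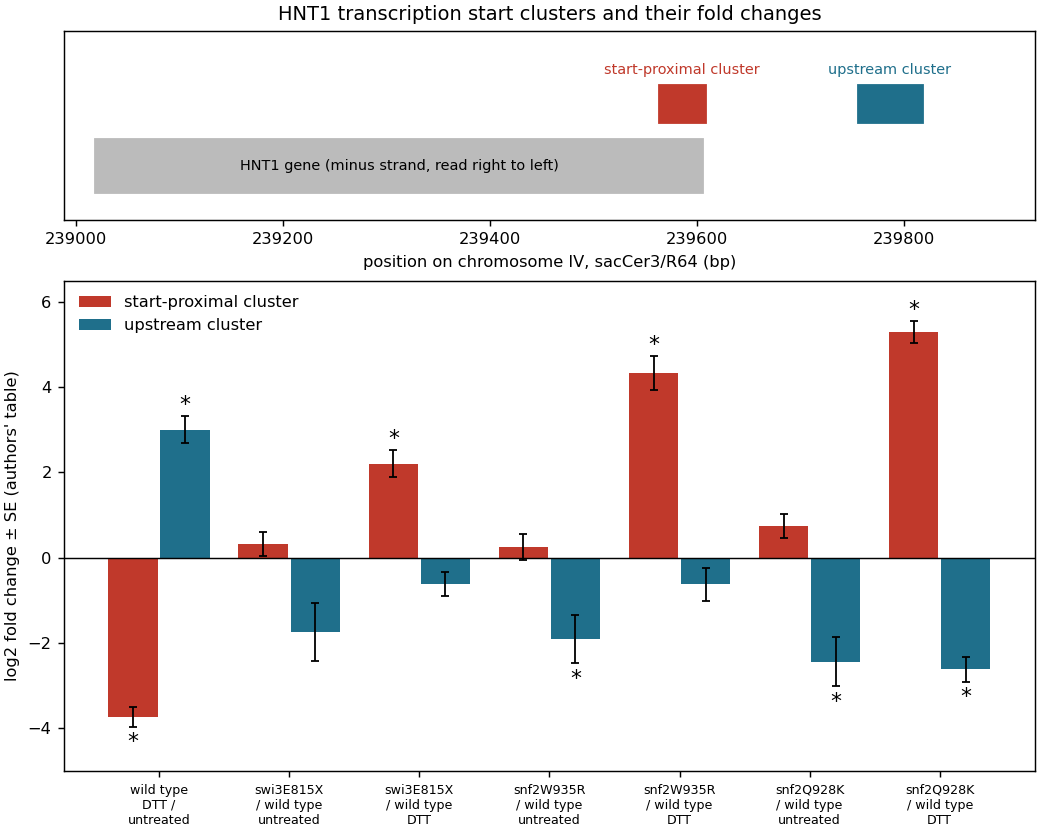
Map of the HNT1 locus on chromosome IV with its start-site clusters (position in bp), and log2 fold changes with SE of the authors' deposited tables for each cluster in the 7 comparisons. The start-proximal cluster fell by 3.73 in DTT-treated wild type and was 2.21 to 5.29 higher in the DTT-treated mutants than in DTT-treated wild type.

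At HNT1 (YDL125C, minus strand, IV, 239019 to 239606) DTT shifted start-site use upstream in wild-type cells, and every mutant kept more of the start-proximal use. The start-proximal cluster (239563 to 239608) spans the coding start, with its midpoint inside the coding region. It fell by 3.73 ± 0.23 on the log2 scale in the authors' deposited table (Benjamini-Hochberg adjusted p = 8.44e-55). The upstream cluster (239755 to 239817), 180 bp from the coding start, rose by 3 ± 0.31 in the authors' deposited table (adjusted p = 6.2e-20). Under DTT the start-proximal HNT1 cluster was higher than wild type in swi3E815X by 2.21 ± 0.32 (adjusted p = 2.9e-09), in snf2W935R by 4.33 ± 0.40 (5.7e-25) and in snf2Q928K by 5.29 ± 0.26 (3.7e-89) in the authors' deposited tables. Untreated, its log2 fold changes in the authors' deposited tables were 0.32 in swi3E815X, 0.25 in snf2W935R and 0.74 in snf2Q928K, none called. The effect of each mutant on this HNT1 cluster was larger under DTT than untreated, by 1.89 in swi3E815X (Benjamini-Hochberg adjusted p = 0.0211), 4.09 in snf2W935R (1.54e-12) and 4.55 in snf2Q928K (7.47e-29). The swi3E815X effect on HNT1 was smaller than that of snf2W935R by a log2 difference of -2.13 (adjusted p = 0.0135, Benjamini-Hochberg) and than that of snf2Q928K by -3.08.

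The upstream HNT1 cluster differed between mutants. Under DTT it was lower in snf2Q928K than in DTT-treated wild type, by a log2 fold change of -2.61 ± 0.30 in the authors' deposited table (Benjamini-Hochberg adjusted p = 1.3e-16). In swi3E815X and snf2W935R its log2 fold changes under DTT were -0.62 and -0.63 in the authors' deposited tables, not called. That HNT1 cluster was higher in both than in snf2Q928K, by 1.99 each (adjusted p = 0.000283 for swi3E815X and 0.0288 for snf2W935R, Benjamini-Hochberg). Untreated, the upstream HNT1 cluster was lower in snf2W935R (-1.91, adjusted p = 0.032) and snf2Q928K (-2.44, adjusted p = 0.0011) in the authors' deposited tables, and at -1.74 in swi3E815X was not called. The snf2Q928K deficit was thus present without DTT and does not show a lost induction by DTT.

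In untreated swi3E815X cells, phosphate genes were lower and sulfur amino acid genes higher than in wild type. This comparison asks what truncation of Swi3 does without stress. It changed 94 clusters, 24 higher and 70 lower, 91 of them at least 2-fold. Increases in the authors' deposited table were largest for PRM7, a pheromone-regulated gene (log2 fold change 4.97 ± 0.86, inside its coding region), the arginine genes ARG1 (2.55) and ARG56 (2.26), MET13 (2.47) and the intergenic cluster 504 (2.39). YKL162C-A (log2 fold change 2.29), HPF1 (1.96), STR3 (1.78), carbonic anhydrase NCE103 (1.75) and SPO24 (1.62) completed the 10 highest in the authors' deposited table. Lowest in the authors' deposited table were PHO5 (log2 fold change -5.14 ± 0.69), PHM6 (-3.72), the secreted glycoprotein YGP1 (-3.61 ± 0.34), the intergenic clusters 993 (-3.46) and 6826 (-2.92), and SPL2 (-3.44), a regulator of phosphate uptake. A cluster inside RPS23A (log2 fold change -3.31), the phosphate transporter PHO89 (-3.06), YCR013C (-2.99) and YHR033W (-2.74) followed in the authors' deposited table.

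Of the phosphate response list in untreated swi3E815X, 6 of 11 fell and none rose (9 lower and 1 higher adjusted over the list alone; median log2 fold change -1.56, cameraPR adjusted p = 5.79e-33), VTC3 of polyphosphate synthesis among them at -2.48 ± 0.27 in the authors' deposited table. Sulfur amino acid synthesis had 6 of 18 higher (9 adjusted over the list alone; adjusted p = 1.35e-11, cameraPR), and the respiratory chain 1 of 35, ATP14 (1 adjusted over the list alone; adjusted p = 0.000168). Iron uptake (median -0.76, 0 of 12 called, 3 lower adjusted over the list alone; adjusted p = 0.000168, cameraPR) and MATa-specific genes (median -0.76, 0 of 6 called, 4 lower adjusted over the list alone; adjusted p = 0.000357) moved down as lists. Glycolysis was lower as a list (1 of 17, TDH3, and 3 adjusted over the list alone; median -0.44, adjusted p = 4.54e-05, cameraPR), and the wild-type libraries of the swi3 tables were themselves higher in this list than those of the snf2 tables by a median of 0.69. Vesicle coats passed with 0 of 20 members called and 0 adjusted over the list alone (median -0.16, adjusted p = 0.043, cameraPR), a call lost at the higher correlation (adjusted p = 0.176) and with log2 fold changes (adjusted p = 0.193). The textbook Swi/Snf-dependent genes had 2 of 8 lower, PHO5 and PHO84, and 1 higher, ARG1 (3 and 1 adjusted over the list alone; adjusted p = 0.00982, cameraPR), and the call was lost on ranks (adjusted p = 0.306). The other 20 lists did not pass.

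Under DTT, swi3E815X cells had lower iron uptake, phosphate and general stress genes than wild type. The comparison asks what the same truncation does to the stressed cell. It changed 72 clusters, 11 higher and 61 lower, each by at least 2-fold. Besides HNT1, the higher clusters in the authors' deposited table included PRM7 (log2 fold change 3.12 ± 0.37), a cluster inside TAD2 (2.10 ± 0.37), the intergenic cluster 1756 (2.01), aconitase ACO1 (1.81), RKM5 (1.58), SHM2 (1.29), the mitochondrial carrier ODC2 (1.25) and a secondary cluster of ERG11 (1.23) of ergosterol synthesis, whose main cluster was not called. The lowest in the authors' deposited table were NCA3 (log2 fold change -4.68 ± 0.56), SPL2 (-4.60), YHR033W (-4.09), ARN2 (-3.66 ± 0.39), PHO84 (-2.85), YCR051W (-2.85), glycogen synthase GSY1 (-2.81), RNR4 of ribonucleotide reductase (-2.72), the a-factor gene MFA1 (-2.70 ± 0.29) and the intergenic cluster 5258 (-2.69). SER3, phosphoglycerate dehydrogenase of serine synthesis, was lower in the authors' deposited table by a log2 fold change of -1.45 (Benjamini-Hochberg adjusted p = 0.0037), while INO1 (-0.89) and KAR2 (-0.09) were not called.

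Of 12 iron uptake genes in DTT-treated swi3E815X, 6 fell (9 adjusted over the list alone; median log2 fold change -1.35, cameraPR adjusted p = 1.8e-21), and the wild-type libraries of the swi3 tables were lower in this list than those of the snf2 tables by a median of -0.94. The phosphate list had 3 of 11 lower (7 adjusted over the list alone; median -1.44, adjusted p = 1.87e-13, cameraPR) and general stress 4 of 13 (6 adjusted over the list alone; median -0.82, adjusted p = 9.72e-10). Among them PGM2 of storage carbohydrate metabolism was at -2.22 ± 0.57 and MSC1 at -1.92 ± 0.41 in the authors' deposited table. Of MATa-specific genes 1 of 6 fell, MFA1 (2 adjusted over the list alone; adjusted p = 2.97e-06, cameraPR), of phospholipid synthesis 1 of 12, OPI3 (3 adjusted over the list alone; adjusted p = 0.000305), and of the textbook list 2 of 9, PHO84 and SER3 (3 adjusted over the list alone; adjusted p = 0.000106, lost on ranks at adjusted p = 0.206). The median of that textbook list was -0.35, and 0.00 with members under the floor at their bound. Ergosterol synthesis had 1 of 23 lower, ERG1 (2 adjusted over the list alone; cameraPR adjusted p = 0.00664, and 0.0527 at the higher correlation), and G2/M 1 of 6, NCE102 (1 adjusted over the list alone; adjusted p = 0.0125, and 0.149 on ranks). In 5 lists that rose, none of the members was called. These were ribosomal proteins (median 0.27, adjusted p = 6.39e-09, cameraPR), glycolysis (0.35, adjusted p = 0.000305), amino acid synthesis (0.24, adjusted p = 0.0026), the respiratory chain (0.27, adjusted p = 0.00664, and 0.0783 at the higher correlation) and ribosome biogenesis (0.18, adjusted p = 0.0129, and 0.107 at the higher correlation). Adjusted over the list alone, 1 glycolysis gene and 1 amino acid gene were higher. The other 15 lists did not pass.

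Untreated snf2W935R cells had lower phosphate and iron uptake genes and higher ARG1, ARG3 and ARG4. The comparison asks what this substitution in the Snf2 ATPase does without stress. It changed 142 clusters, 49 higher and 93 lower, 141 of them at least 2-fold. The authors' deposited table had SPL2 at least 285.7-fold lower, TIS11, which degrades messenger RNA in iron shortage, at least 19.5-fold and SNA3 at least 16.9-fold. Also low in the authors' deposited table were PHM6 (log2 fold change -5.30), YRO2 (-5.10), PHO89 (-4.61), the siderophore transporter ENB1 (-4.31), YGP1 (-3.89 ± 0.39) and the intergenic clusters 781 (-4.57) and 1226 (-3.94). Highest in the authors' deposited table were a cluster inside MEP3, at least 112.9-fold, ARG1 (log2 fold change 4.27 ± 0.49), the intergenic clusters 5511 (3.78) and 469 (2.29), and YLR149C-A (3.05). ARG56 (log2 fold change 2.71), ARG3 (2.69), TDA2 (2.47), ODC2 (2.44 ± 0.33) and a secondary cluster of ERG3 (2.30), whose main cluster was not called, followed in the authors' deposited table. The fitted MEP3 value there, 24.11, rests on an arm near 0, and its difference between treatments had an SE of 4.86. Whether both mutant libraries carried the MEP3 counts is unknown, so its place among the highest is uncertain. In untreated swi3E815X, clusters 469 and 5511 had mean normalized counts of 129.5 and 302.8 at uncalled log2 fold changes of -0.46 and 0.16 in the authors' deposited table. In untreated snf2W935R the counts were 66.3 and 228.8. The wild-type means at both were thus lower in the snf2 tables, and these sizes depend on the wild-type set. SER3, at a log2 fold change of 0.74 in the authors' deposited table, was not called.

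The phosphate list in untreated snf2W935R had 8 of 11 lower (9 adjusted over the list alone; median log2 fold change -2.86, cameraPR adjusted p = 1.05e-38), with VTC3 at -3.50 ± 0.29 and PHO84 at -2.17 ± 0.32 in the authors' deposited table. Iron uptake had 7 of 12 lower (9 adjusted over the list alone; median -3.04, or -2.61 with members under the floor at their bound; adjusted p = 2.86e-22, cameraPR), with FIT3, a cell wall protein that retains siderophores, at -3.09 ± 0.36 in the authors' deposited table. The wild-type libraries of the snf2 tables were themselves higher in the iron list than those of the swi3 tables, a median of -0.66 as swi3 over snf2 sets. The depth of the iron medians of both untreated snf2 mutants thus depends on the wild-type set. Amino acid synthesis had 4 of 29 higher (5 adjusted over the list alone; adjusted p = 3.91e-07, cameraPR), ARG1, ARG3, ARG4 and ARO3. The respiratory chain (median 0.68, adjusted p = 4.97e-11, cameraPR), sulfur amino acid synthesis (0.44, adjusted p = 0.00368) and ribosomal proteins (0.21, adjusted p = 0.000211, and 0.0555 at the higher correlation) moved up as lists with no member called and none adjusted over the list alone. The wild-type libraries of the snf2 tables were lower than those of the swi3 tables in ribosomal proteins by a median of 0.36, more than that shift, and in the respiratory chain by 0.23. The ribosomal call thus depends on the wild-type set. Heat shock chaperones had 3 of 20 lower (4 adjusted over the list alone; adjusted p = 0.00131, cameraPR), with HSP78 at -1.77 ± 0.36 in the authors' deposited table, general stress 2 of 13, GSY1 and DDR2 (4 adjusted over the list alone; adjusted p = 0.000548), and daughter cell genes 2 of 14, HO and PST1 (2 adjusted over the list alone; adjusted p = 0.00131). The wild-type libraries of the snf2 tables were higher in general stress genes than those of the swi3 tables, a median of -0.84 as swi3 over snf2 sets, and in daughter cell genes, -0.76. At DDR2 the difference between the sets exceeded its log2 fold change of -1.70, so that call depends on the wild-type set. MATa-specific genes had 3 of 6 lower, BAR1, AGA2 and MFA1 (4 adjusted over the list alone; adjusted p = 0.000303, cameraPR, and 0.0943 on ranks), and hexose transport 1 of 6, HXT1 (2 adjusted over the list alone; adjusted p = 0.00368, and 0.0636 with log2 fold changes). The other 17 lists did not pass.

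With DTT, snf2W935R cells kept higher ribosomal protein and histone genes than wild type and lower iron, phosphate and chaperone genes. Changes reached 279 clusters, 132 higher and 147 lower, 276 of them at least 2-fold. Besides HNT1, the highest in the authors' deposited table were the intergenic clusters 976 (log2 fold change 5.10), 8331 (4.42), 1756 (3.89), 617 (3.74) and 6274 (3.08), ISU1, an iron-sulfur scaffold (3.98), TAD2 (3.54 ± 0.38) and SRL1 (2.98). Cluster 976 had a mean normalized count of 60.4 here, but of 173.6 at an uncalled log2 fold change of 0.20 in DTT-treated swi3E815X in the authors' deposited tables. Its wild-type mean was thus far lower in the snf2 tables, and its size here depends on the wild-type set. KAR2 changed at separate clusters in opposite directions. Its main cluster (X, 381290 to 381316) was lower in the authors' deposited table by a log2 fold change of -1.83 ± 0.37 (adjusted p = 6.1e-05, Benjamini-Hochberg). A KAR2 cluster 446 bp upstream of the coding start (X, 380830 to 380932) was at least 18.3-fold higher in the authors' deposited table (adjusted p = 3e-05, Benjamini-Hochberg). The iron genes LSO1 (log2 fold change -7.67 ± 1.39), ARN2 (-5.66 ± 0.44), FIT2 (-5.48 ± 0.46), haem oxygenase HMX1 (-5.41) and ENB1 (-4.21 ± 0.37) were lowest in the authors' deposited table, with SPL2 (-5.28), NCA3 (-4.47), DUR12 (-4.44), SNA3 (-4.29) and the siderophore transporter SIT1 (-4.02). SER3 (0.35) and INO1 (-0.87) were not called in the authors' deposited table.

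Of the iron list in DTT-treated snf2W935R, 9 of 12 fell (10 adjusted over the list alone; median log2 fold change -3.92, cameraPR adjusted p = 1.67e-47), and of the phosphate list 6 of 11 (7 adjusted over the list alone; median -2.45, adjusted p = 3.04e-11). The wild-type libraries of the snf2 tables under DTT were higher in both lists than those of the swi3 tables. The medians as swi3 over snf2 sets were -0.94 for iron and -0.49 for phosphate. The depth of both list medians in the snf2 mutants thus depends on the wild-type set. Heat shock chaperones had 6 of 20 lower (9 adjusted over the list alone; adjusted p = 8.19e-09, cameraPR) and general stress 7 of 13 (8 lower and 1 higher adjusted over the list alone; adjusted p = 6.36e-08), with HSP78 at -2.88 ± 0.34, the cytosolic Hsp70 SSA1 at -2.93 ± 0.39 and TFS1 at -2.28 ± 0.35 in the authors' deposited table. Higher were 26 of 132 genes in the ribosomal protein list (45 adjusted over the list alone; median 0.60, adjusted p = 3.93e-17, cameraPR) and 2 of 10 histone genes, HHF1 and HTB2 (5 adjusted over the list alone; adjusted p = 0.00191). Ribosome biogenesis had 1 of 33 higher, DBP3 (4 adjusted over the list alone; adjusted p = 0.0048, cameraPR, and 0.0781 at the higher correlation), and the respiratory chain 4 of 35, among them SDH3 (10 adjusted over the list alone; adjusted p = 0.00191, and 0.0531 at the higher correlation). In this respiratory list the wild-type libraries of the snf2 tables were lower by a median of 0.35. The list median was 0.51. The other 20 lists did not pass.

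In untreated snf2Q928K cells, SER3 and the amino acid synthesis list were higher, and HO and the phosphate and iron uptake lists lower. This substitution in the Snf2 ATPase changed 340 clusters, 146 higher and 194 lower, 324 of them at least 2-fold. SER3 (V, 322635 to 322693) rose by a log2 fold change of 5.89 ± 0.28 in the authors' deposited table (Benjamini-Hochberg adjusted p = 6e-96). The authors' deposited table had HO at least 123.2-fold lower, SPL2 at least 328.9-fold and SNA3 at least 19.3-fold. Other low clusters in the authors' deposited table were the peptide transporter PTR2 (log2 fold change -6.93 ± 0.59), PHM6 (-6.15), ENB1 (-6.03), an upstream cluster of the Swi/Snf subunit gene SNF11 (-5.82 ± 0.67), YRO2 (-5.60), PHO89 (-5.38) and SIT1 (-4.68). Besides SER3, among the highest in the authors' deposited table were IMD2 of guanine nucleotide synthesis, at least 19.7-fold, HIS4, at the cluster inside its coding region, at least 18.4-fold, ARG1 (log2 fold change 4.47 ± 0.43), the intergenic clusters 4392 (4.33) and 4512 (4.12), a secondary cluster of ERG11 (3.58 ± 0.56), ARG56 (3.21 ± 0.40) and YBR085C-A (3.06 ± 0.29). The main clusters of HIS4 and ERG11 were not called. IMD2 was also lower in the wild-type libraries of the snf2 tables than in those of the swi3 tables, which were higher by 3.74. At clusters 4392 and 4512 the mean normalized counts in untreated swi3E815X were 54.1 and 36.4, at uncalled log2 fold changes of 1.17 and 0.09 in the authors' deposited table. In untreated snf2Q928K they were 61.6 and 72.05. The wild-type means at both were thus lower in the snf2 tables, and these sizes depend on the wild-type set.

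The phosphate list had 8 of 11 lower in untreated snf2Q928K (9 adjusted over the list alone; median log2 fold change -2.55, cameraPR adjusted p = 1.56e-18), with VTC3 at -3.93 ± 0.28 in the authors' deposited table. Of the iron list 7 of 12 fell and the iron permease FTR1 rose (8 and 1 adjusted over the list alone; median -1.94, or -1.91 with members under the floor at their bound; adjusted p = 4.05e-09, cameraPR), FTR1 by 2.21 ± 0.32 in the authors' deposited table. Daughter cell genes had 9 of 14 lower (10 adjusted over the list alone; median -1.94, adjusted p = 9.22e-13, cameraPR), with BUD9 at -3.23 ± 0.44 in the authors' deposited table. Amino acid synthesis had 11 of 29 higher and 1 lower (11 and 2 adjusted over the list alone; adjusted p = 1.66e-09, cameraPR) and sulfur amino acid synthesis 4 of 18 higher (10 adjusted over the list alone; adjusted p = 1.06e-06), with ARG4 at 1.98 ± 0.30 and MET13 at 1.95 ± 0.43 in the authors' deposited table. Heat shock chaperones had 4 of 20 lower (4 adjusted over the list alone; adjusted p = 0.0072, cameraPR). For general stress 3 of 13 were lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00365, cameraPR, and 0.0632 with log2 fold changes) and for MATa-specific genes 4 of 6 (4 adjusted over the list alone; adjusted p = 0.0055, and 0.0586 with log2 fold changes). The wild-type libraries of the snf2 tables were higher in general stress and daughter cell genes. The medians were -0.84 and -0.76 as swi3 over snf2 sets, so the depth of both lists here depends on the wild-type set. Hexose transport had 1 of 6 lower, HXT4 (2 adjusted over the list alone; adjusted p = 0.00988, cameraPR, and 0.169 on ranks), and G2/M 2 of 6, NCE102 and HST3 (2 adjusted over the list alone; adjusted p = 0.0459, and 0.0836 on ranks, 0.0821 with log2 fold changes and 0.0826 at the higher correlation). In the ribosomal protein list 1 of 132 rose, RPL23B (0 adjusted over the list alone; adjusted p = 0.0082, cameraPR, and 0.196 at the higher correlation and 0.0527 with log2 fold changes), and in the respiratory chain 1 of 35, CYC1 (1 adjusted over the list alone; adjusted p = 0.0082, and 0.0826 at the higher correlation). Their medians of 0.20 and 0.28 stand against differences of 0.36 and 0.23 by which the wild-type libraries of the snf2 tables were lower. These calls thus depend on the wild-type set. The textbook Swi/Snf-dependent genes went both ways, with SER3 and ARG1 higher and HO, PHO84 and PHO5 lower (2 and 3 adjusted over the list alone). Their median was 0.17 (0.00 with members under the floor at their bound), their mean -0.45 and the test upward (adjusted p = 0.00913, cameraPR), and it turned downward with log2 fold changes (adjusted p = 0.0508). On that scale HO enters at a fitted -12.22, which rests on an arm near 0, against 5.89 for SER3 in the authors' deposited table. The other 15 lists did not pass.

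With DTT, snf2Q928K cells differed from wild type at more clusters than in any other mutant table, 754 in all, 381 higher and 373 lower, 560 of them at least 2-fold. Ribosomal protein, glycolytic and sulfur amino acid genes were higher, and iron, phosphate, stress and chaperone genes lower. The highest in the authors' deposited table, besides HNT1, were the intergenic clusters 976 (log2 fold change 5.69), 1756 (4.75), 4985 (3.89), 6170 (3.85) and 8331 (3.50), PRY2 (4.15), SER3 (3.72 ± 0.28), ODC2 (3.31 ± 0.26) and TAD2 (3.23 ± 0.28). The size at cluster 976 again depends on the wild-type set, since its wild-type mean under DTT was far lower in the snf2 tables than in the swi3 tables. Iron genes LSO1 (log2 fold change -8.94 ± 1.5), ENB1 (-7.23 ± 0.38), SIT1 (-6.74 ± 0.43), FIT2 (-5.87) and ARN2 (-5.67) were among the lowest in the authors' deposited table, with SPL2 (-6.22), HO (-5.52 ± 0.89), the intergenic cluster 6111 (-5.06), SNA3, at least 23.1-fold lower, and ERG27, at least 18.1-fold lower. KAR2 was lower at its main cluster in the authors' deposited table by a log2 fold change of -1.54 ± 0.27 (adjusted p = 5.1e-07, Benjamini-Hochberg) and at least 15.7-fold higher at the upstream one (adjusted p = 3.6e-05). INO1 was lower in the authors' deposited table by a log2 fold change of -1.11 (adjusted p = 0.013, Benjamini-Hochberg).

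Of 12 iron genes 11 fell in DTT-treated snf2Q928K (11 adjusted over the list alone; median log2 fold change -3.72, cameraPR adjusted p = 2.91e-43). The phosphate list had 6 of 11 lower and 1 higher (7 and 1 adjusted over the list alone; median -1.97, adjusted p = 4.5e-08, cameraPR), general stress 9 of 13 lower (11 adjusted over the list alone; median -2.15, adjusted p = 4.6e-10) and heat shock chaperones 7 of 20 lower (7 adjusted over the list alone; adjusted p = 7.47e-05). Hexokinase HXK1 (log2 fold change -3.43 ± 0.39), TFS1 (-2.15 ± 0.29) and SSA1 (-2.66 ± 0.23) were examples in the authors' deposited table. Higher were 73 of 132 genes in the ribosomal protein list (88 adjusted over the list alone; median 0.72, adjusted p = 2.05e-25, cameraPR), 8 of 33 of ribosome biogenesis (13 adjusted over the list alone; adjusted p = 1.34e-05) and 5 of 10 histone genes (5 adjusted over the list alone; adjusted p = 0.0051). Glycolysis had 8 of 17 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 2.18e-05, cameraPR), with ENO1 at 1.73 ± 0.25, TDH2 at 1.63 ± 0.22 and TDH3 at -1.56 ± 0.31 in the authors' deposited table. Sulfur amino acid synthesis had 7 of 18 higher (7 adjusted over the list alone; adjusted p = 4.13e-05, cameraPR) and amino acid synthesis 9 of 29 higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 7.47e-05), with MET6 at 2.51 ± 0.28 and ILV3 at 1.67 ± 0.27 in the authors' deposited table.

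Several weaker calls in DTT-treated snf2Q928K depended on the setting. The ER folding list had 4 of 16 lower, KAR2, SIL1, EUG1 and LHS1 (4 adjusted over the list alone; adjusted p = 0.0329, cameraPR), lost at the higher correlation (adjusted p = 0.0882) and with log2 fold changes (adjusted p = 0.227). Phospholipid synthesis had 5 of 12 lower, among them OPI3 and INO1 (7 adjusted over the list alone; adjusted p = 0.0303, cameraPR), and daughter cell genes 3 of 14, PST1, HO and DSE1 (4 adjusted over the list alone; adjusted p = 0.0272). Thiol redox had 6 of 15 lower, among them GPX2, and CCP1 higher (7 and 2 adjusted over the list alone; adjusted p = 0.0219, cameraPR), and the respiratory chain 5 of 35 higher (6 adjusted over the list alone; adjusted p = 0.0104). Each of these 4 calls was lost at the higher correlation, with an adjusted p of 0.0746 by cameraPR. Hexose transport had 2 of 6 higher, HXT2 and HXT3 (2 adjusted over the list alone; adjusted p = 0.0218, cameraPR, and 0.179 on ranks), at a median of 0.94, or 0.71 with members under the floor at their bound. Of MATa-specific genes 2 of 6 fell, MFA1 and BAR1 (2 adjusted over the list alone; adjusted p = 0.0431, cameraPR, and 0.0746 at the higher correlation, 0.157 on ranks and 0.267 with log2 fold changes). Of G2/M genes 1 of 6 fell, NCE102 (1 adjusted over the list alone; adjusted p = 0.0496, cameraPR, and 0.081 at the higher correlation and 0.595 on ranks). The other 10 lists did not pass.

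**Figure D2:**
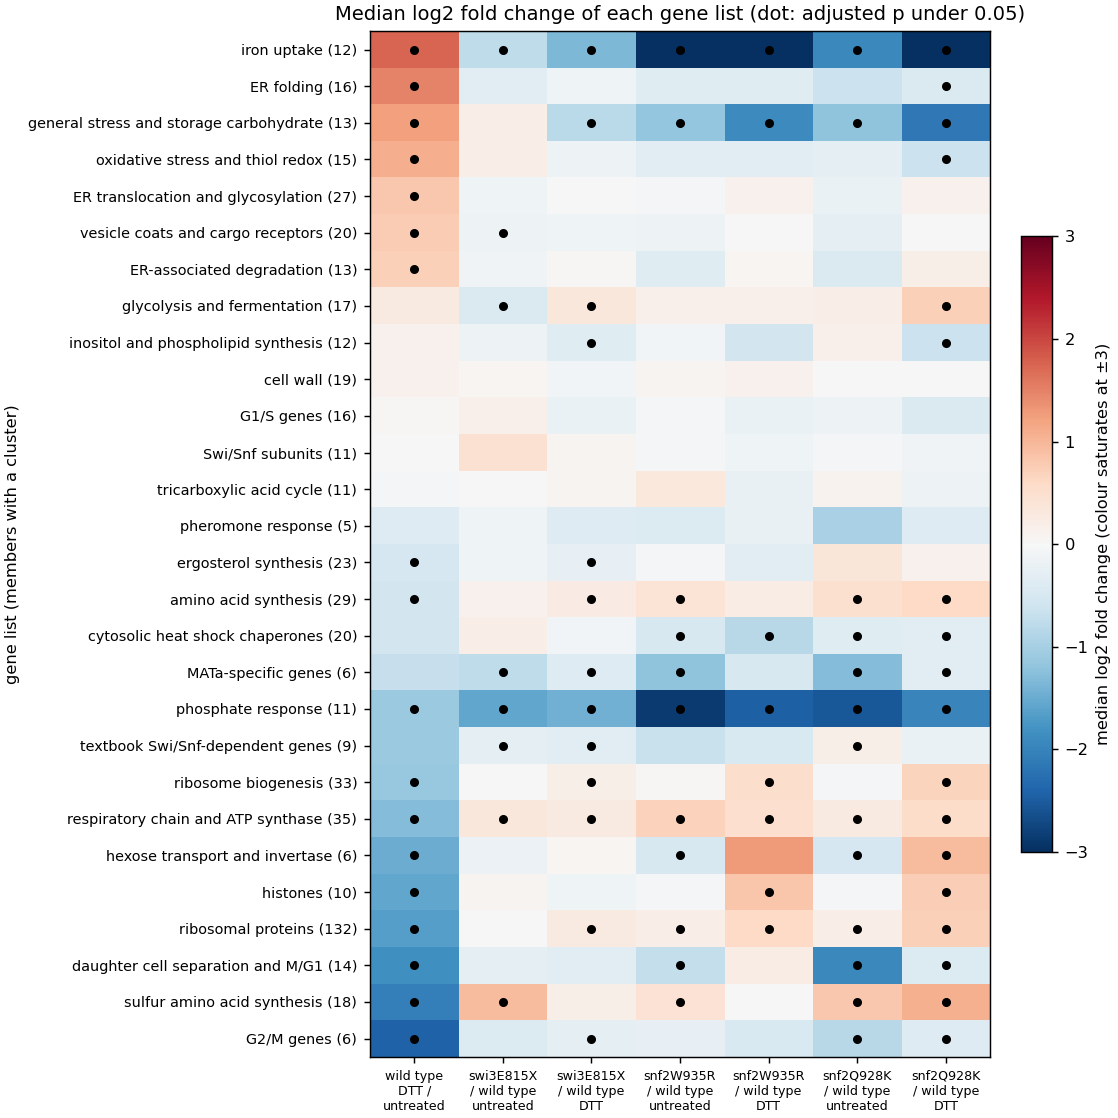
Heat map of the median log2 fold change of each gene list (lines) in the 7 comparisons (columns), with a dot where the cameraPR adjusted p was under 0.05. The phosphate and iron lists are lower in all 6 mutant comparisons, at medians of -1.56 and -0.76 in untreated swi3E815X and of -1.97 and -3.72 in DTT-treated snf2Q928K.

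The phosphate and iron lists and YGP1 were lower in all 3 mutants, although no member of the iron list was called in untreated swi3E815X. The swi3E815X tables and the snf2 tables rest on separate sets of wild-type libraries, and no mutant was compared with both. Untreated, 5 clusters were higher in all 3 mutants, ARG1, ARG4, ARG56, ODC2 and SPO24, and 25 were lower. Under DTT, 6 were higher, HNT1, PRM7, the secondary cluster of ERG11, TAD2, ODC2 and the intergenic cluster 1756, and 41 were lower. Under both treatments, ODC2 was the 1 cluster higher in all 3 mutants, and 12 were lower, among them PHO84, SPL2, VTC3, YGP1, RNR4, ERG1, BAT2 and the iron regulator AFT1. PHO84 had log2 fold changes in the authors' deposited tables of -1.56 and -2.85 in swi3E815X, -2.17 and -3.69 in snf2W935R, and -2.17 and -3.74 in snf2Q928K, untreated and with DTT. YGP1 had values in the authors' deposited tables from -3.89 to -2.13. ARG4, VTC3, ERG1, BAT2 and AFT1 are listed here after their values were seen.

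**Figure D3:**
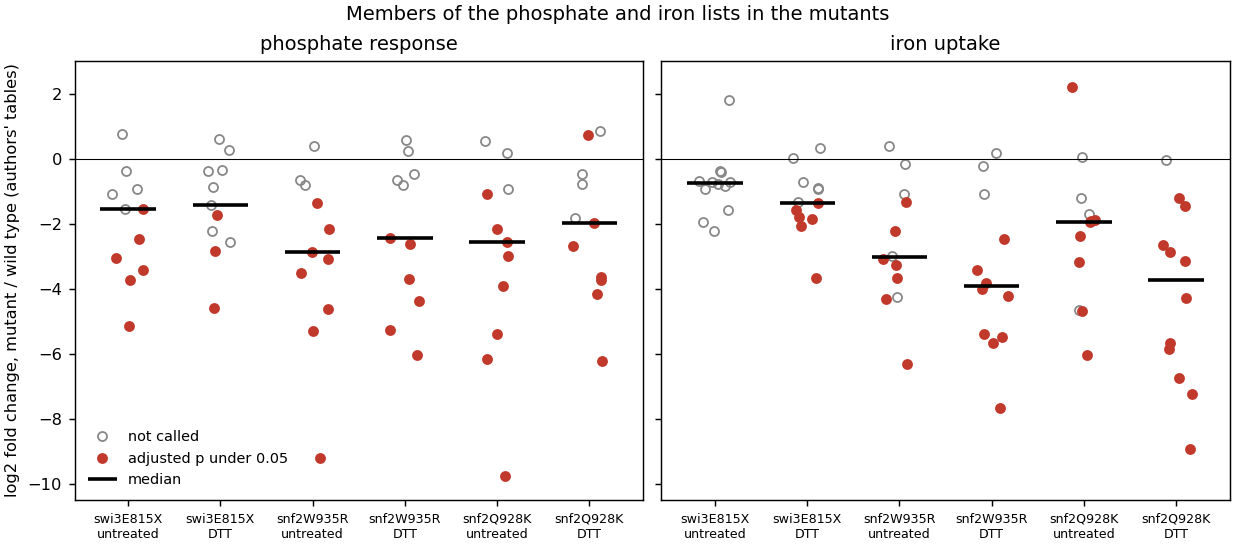
Log2 fold change, mutant over wild type, of each member of the phosphate and iron lists (points) in the 6 mutant tables, with the list median as a bar. Medians ran from -2.86 to -1.44 for the phosphate list and from -3.92 to -0.76 for the iron list.

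The overlap of calls between mutants exceeded the number expected from independent calls in every pair. Untreated, swi3E815X and snf2W935R shared 5 higher clusters (0.227 expected) and 28 lower ones (1.26), and swi3E815X and snf2Q928K shared 14 (0.677) and 32 (2.62). The snf2 mutants shared 35 higher (1.35 expected) and 78 lower (3.48), but they have the same wild-type libraries, so part of their overlap can come from those. Under DTT the snf2 pair shared 105 higher clusters (9.69 expected) and 121 lower (10.6), swi3E815X and snf2W935R 6 (0.28) and 44 (1.73), and swi3E815X and snf2Q928K 10 (0.807) and 52 (4.38). The expected numbers do not allow for clusters that are more readily called in every table. The covariance of the snf2 pair's log2 fold changes across clusters was 0.512 untreated against 0.157 in simulations with shared controls, and 0.633 against 0.129 under DTT. For swi3E815X, with separate controls, it was 0.148 with snf2W935R and 0.2315 with snf2Q928K untreated, and 0.178 and 0.254 under DTT. Simulated covariances of those pairs lay between -0.001 and 0.001. Clusters are not independent replicates, and no p is given for these covariances.

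The wild-type libraries of the swi3 tables and of the snf2 tables differed from each other. Of the clusters compared, 108 of 3569 differed untreated (70 higher in the swi3 set) and 25 of 3860 under DTT (14 higher). Untreated, the swi3 set was higher in ENO2 by 2.27, in the alcohol dehydrogenase ADH1 by 2.39 and in IMD2 by 3.74 on the log2 scale, and lower in DDR2 (-1.93) and GPD1 (-1.71), which were chosen here after their values were seen, as was IMD2 for this comparison. In the same direction as a list call, the difference between the sets was at least as large as the list median for glycolysis and the textbook genes in untreated swi3E815X. This also held for ribosomal proteins and daughter cell genes in untreated snf2W935R, and for ribosomal proteins and the textbook genes in untreated snf2Q928K. It was close to that median for hexose transport in both untreated snf2 mutants (-0.46 against -0.48 and -0.51). The 2 sets come from strains with different complemented genes, and strain and library preparation were not separated by the design.

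SER3 and PTR2 separated snf2Q928K from the other mutants. This comparison asks whether the substitutions act alike. Untreated, 45 clusters differed between swi3E815X and snf2Q928K (30 higher in swi3E815X), 13 between swi3E815X and snf2W935R (4 higher in swi3E815X) and 9 between the snf2 mutants (7 higher in snf2W935R). Under DTT the counts were 74 (45 higher in swi3E815X), 29 (18 higher in swi3E815X) and 15 (13 higher in snf2W935R). The swi3E815X counts also hold differences between the wild-type sets, which were called at 108 clusters untreated and 25 under DTT. The snf2 pair shares its wild-type libraries, so its counts cannot be set directly against those of swi3E815X. SER3 was lower in snf2W935R than in snf2Q928K by a log2 difference of -5.15 untreated (adjusted p = 2.72e-18, Benjamini-Hochberg) and -3.38 with DTT (adjusted p = 4.97e-08), and in swi3E815X by -5.59 (adjusted p = 8.53e-13) and -5.18 (adjusted p = 4.88e-28). PTR2 was higher in snf2W935R than in snf2Q928K by 5.03 untreated (adjusted p = 2.22e-10, Benjamini-Hochberg) and 3.03 with DTT (adjusted p = 0.00049), and in swi3E815X by 6.23 (adjusted p = 2.47e-14) and 3.86 (adjusted p = 3.63e-08). The siderophore transporter ENB1 was higher in snf2W935R than in snf2Q928K by 3.02 with DTT (adjusted p = 3.73e-05, Benjamini-Hochberg). SPL2 was higher in swi3E815X than in snf2W935R by 5.77 untreated, a fitted value that rests on an arm near 0. With an SE for fully shared controls, which applies to the snf2 pair, the counts between the snf2 mutants were 39 untreated and 67 with DTT.

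The effects of the mutations changed with DTT at few clusters in swi3E815X and more in the snf2 mutants. The comparison asks which effects of the mutations depend on ER stress. In swi3E815X 2 clusters differed, HNT1 and ADE17 of purine synthesis (2.60, adjusted p = 0.0211, Benjamini-Hochberg; named after its value was seen), against 198 at an unadjusted p under 0.05. In snf2W935R 45 differed (30 more positive under DTT), and in snf2Q928K 73 (40 more positive). SER3 rose less under DTT in snf2Q928K, with a difference of -2.17 (adjusted p = 4.17e-05, Benjamini-Hochberg), and FIT2 and FTR1 shifted down by -3.47 (adjusted p = 4.51e-07) and -2.25 (adjusted p = 0.000148). TAD2 shifted up by 3.62 in snf2W935R (adjusted p = 0.02, Benjamini-Hochberg) and 2.61 in snf2Q928K (adjusted p = 0.0427). As a list, ribosomal proteins shifted up under DTT in each mutant, by medians of 0.37 (cameraPR adjusted p = 1.2e-12), 0.46 (3.17e-06) and 0.56 (1.16e-14) in swi3E815X, snf2W935R and snf2Q928K. Iron uptake shifted down in snf2W935R (median -0.83, adjusted p = 0.0146, cameraPR) and snf2Q928K (median -1.86, adjusted p = 1.37e-10), and was not called in swi3E815X (adjusted p = 0.788). The median difference between the wild-type sets, as swi3 over snf2 sets, went from -0.66 untreated to -0.94 with DTT in the iron list. Against the other set the snf2 shifts in this list would thus be smaller. In ribosomal proteins that difference went from 0.36 to 0.15. Against the other set the swi3E815X shift would thus be smaller and those of the snf2 mutants larger.

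**Figure D4:**
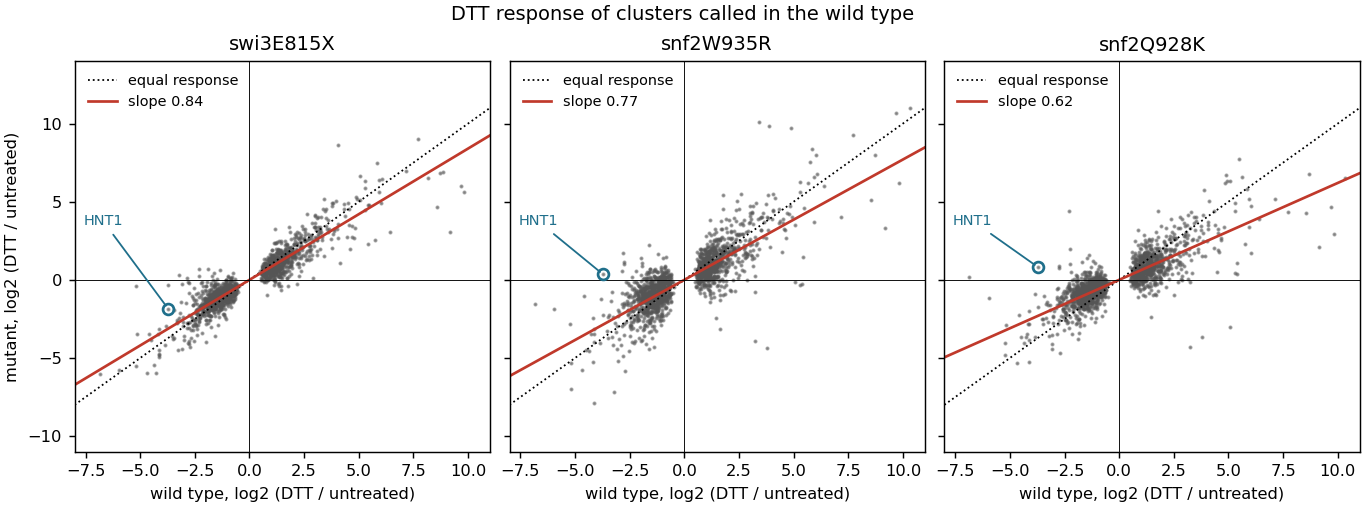
DTT response of each mutant (log2 fold change, DTT over untreated) against that of wild type for the clusters called in wild type that had at least 50 mean normalized counts there, with a line of the fitted slope and 1 panel per mutant. Slopes were 0.84 in swi3E815X, 0.77 in snf2W935R and 0.62 in snf2Q928K.

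The wild-type DTT response was kept in direction at most clusters in every mutant, and its size was smaller. Of the 1751 clusters called in wild type, those with at least 50 mean normalized counts in the wild-type table and a value in the mutant were used. Over 1537 such clusters, 97.5% had the same sign in swi3E815X, with a slope of 0.84. The figures were 88.2% and 0.77 in snf2W935R, over 1538 clusters, and 89.5% and 0.62 in snf2Q928K, over 1537. With the wild-type libraries of each mutant's own tables, chosen after the data were seen, the shares were 98.2%, 93.5% and 94.3%. Clusters chosen for a wild-type call give a slope below 1 through noise alone, by a factor of 0.96 here, and they are not independent replicates. At the start-proximal HNT1 cluster the summed DTT response was -3.73 in wild type, -1.84 in swi3E815X, 0.36 in snf2W935R and 0.83 in snf2Q928K.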

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

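The tests of a generally weaker DTT response, of a lost upstream HNT1 cluster, of released downstream start sites in swi3E815X and snf2W935R and of the wild-type libraries were chosen only after the result was seen. The results here are differences between a mutant's effect under DTT and untreated that passed their own test, as gene lists or at clusters taken by the naming rule, which are part of the 2, 45 and 73 clusters that differed in swi3E815X, snf2W935R and snf2Q928K.

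At the start-proximal HNT1 cluster the difference was 1.89 in swi3E815X, 4.09 in snf2W935R and 4.55 in snf2Q928K. An equally weaker DTT response of all fallen clusters was examined first, in snf2Q928K. Among 48 clusters, HNT1 included, that fell about as far in wild type, the median log2 fold change was 0.58 and HNT1 was highest (97.92 percentile). HNT1 stood at 97.92 in snf2W935R (median 0.45) and at 95.83 in swi3E815X (median 0.07), where CHA1 was higher at 3.93. The next highest were KTR1 at 3.92 in snf2Q928K and COA2 at 4.19 in snf2W935R, the latter close to HNT1 at 4.33, so HNT1 was not alone there. HNT1 was taken up because it was high in these same values, so its rank is no independent support and cannot decide on a generally weaker response. The values show only that HNT1 lay well above the median of these clusters. Release of every start site that lies within 1000 bp downstream of a DTT-induced one by 0.5 log2 units or more was argued against in snf2Q928K and swi3E815X. There 24 such clusters exceeded matched fallen clusters by 0.11 (95% interval -0.23 to 0.37, permutation p = 0.428, adjusted p = 0.642 by Benjamini-Hochberg) and 0.03 (-0.26 to 0.34, permutation p = 0.763, adjusted p = 0.763). In snf2W935R it stays open, at 0.21 (95% interval -0.11 to 0.54, permutation p = 0.236, adjusted p = 0.642 by Benjamini-Hochberg). The gap to the induced site was 147 bp at HNT1 but up to 911 bp in this set. No cluster was assigned to a gene from over 479 bp upstream of its coding start, so many pairs can belong to neighbouring genes. The test thus cannot decide on interference within 1 gene, as at HNT1. A change at HNT1 itself was not tested and stays open. A weaker upstream cluster may contribute in snf2Q928K, where it was lower than in wild type under DTT by a log2 fold change of -2.61, and lower untreated too. In swi3E815X and snf2W935R a loss of at least 1 log2 unit was neither shown nor excluded, since the 95% intervals of the upstream fold change were -1.18 to -0.06 and -1.41 to 0.15, although a loss as large as the wild-type induction of 3 lies outside both.

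The phosphate and iron lists were lower in all 6 mutant tables. High phosphate and iron genes in 1 set of wild-type libraries were argued against as the whole cause, since the largest adjusted p of both lists in the tables against the other set was 0.000168 by cameraPR. The wild-type libraries of the snf2 tables were higher in the iron list than those of the swi3 tables (medians of -0.66 untreated and -0.94 under DTT as swi3 over snf2 sets). The depth of the snf2 medians thus depends on the wild-type set. Clusters with few counts in both arms were argued against as the whole cause. The highest list median among members with at least 50 mean normalized counts was -0.78, for iron uptake in untreated swi3E815X. That minimum applies to the mean of both arms, so a member with few counts in the mutant alone could pass it. A difference in growth state or in phosphate and iron left in the medium may also lower these lists and was not tested, so an effect of Swi/Snf on these genes remains a hypothesis.

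The swi3E815X tables had fewer calls than the snf2Q928K tables. Larger errors in the swi3E815X tables were argued against, since their median SEs were smaller. They were 0.4104 in swi3E815X and 0.4584 in snf2Q928K untreated, and 0.3606 and 0.3708 under DTT. The snf2Q928K fold changes tested with the swi3E815X errors gave 469 calls untreated and 822 under DTT, at least 4.989 times the swi3E815X counts. Smaller errors favour more calls by construction, so these counts add little. A milder mutation and differences between the wild-type libraries may both contribute and were not separated.

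In swi3E815X, the lists that differed between treatments were ribosomal proteins (median 0.37), general stress (-1.23), sulfur amino acid synthesis (-0.63) and glycolysis (0.71). The difference between the wild-type sets, as swi3 over snf2 sets, moved between treatments so that each of these would be smaller against the other set. Its medians untreated and under DTT were 0.36 and 0.15 in ribosomal proteins, -0.84 and -0.23 in general stress, -0.12 and 0.04 in sulfur amino acid synthesis and 0.69 and 0.30 in glycolysis, so the sizes depend on the wild-type set.

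In snf2W935R, 15 of the 45 clusters that differed were taken by the naming rule, 10 of them more positive under DTT. Besides HNT1 these were HXT3 at 1.83, HXT2 at 2.14, SPL2 at 3.92, DDR2 at 2.77, TAD2 at 3.62 and the intergenic cluster 6274 at 3.01, and the ribosomal protein genes RPL29 at 1.69, RPL39 at 1.72 and RPS27A at 2.05. More negative were the intergenic clusters 4392 at -5.41 and 5511 at -2.81, HMX1 at -3.17, NCE102 at -3.10 and MEP3 at -25.81. The fitted values of MEP3 and SPL2 rest on an arm near 0 and give no size. The lists that differed were ribosomal proteins (0.46), heat shock chaperones (-0.47), iron uptake (-0.83), hexose transport (1.60) and histones (1.10).

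In snf2Q928K, 28 of the 73 clusters that differed were taken by the naming rule, 17 of them more positive under DTT. Besides HNT1, more positive were the histone genes HTB2 at 1.67 and HHF1 at 1.58, the hexose transporters HXT3 at 1.62 and HXT2 at 1.77, and ribosomal protein genes RPS8A at 1.43, RPL29 at 1.26, RPL39 at 1.54, RPS27A at 1.45 and RPS31 at 1.88. The others were HO at 6.71, the intergenic cluster 1756 at 2.93, TAD2 at 2.61, PTR2 at 2.86, CCP1 at 1.64, BRX1 at 1.48 and VTC3 at 1.24. More negative were YBR085C-A at -1.74, HIS4 at -7.08, HSP78 at -1.47, SER3 at -2.17, FTR1 at -2.25, the intergenic cluster 4392 at -4.92, OPI3 at -1.55, TFS1 at -2.56, NCE103 at -1.87, FIT2 at -3.47 and NCE102 at -2. The fitted values of HO and HIS4 rest on an arm near 0. The lists that differed were phospholipid synthesis (-0.54), ribosomal proteins (0.56), ribosome biogenesis (0.71), general stress (-0.56), iron uptake (-1.86), hexose transport (1.30), glycolysis (0.60), histones (0.82) and daughter cell genes (1.48).

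The wild-type set of the snf2 tables enters these list differences too. The medians of swi3 over snf2 sets, untreated and under DTT, moved in the direction that enlarges the difference for daughter cell genes (-0.76 and 0.17), hexose transport (-0.46 and -0.10), histones (-0.21 and 0.20), iron uptake (-0.66 and -0.94), phospholipid synthesis (0.45 and 0.21), ribosome biogenesis (-0.20 and 0.08) and heat shock chaperones (-0.08 and -0.14). For ribosomal proteins, general stress and glycolysis they moved against it in the snf2 mutants. These medians do not cover the same members under both treatments in every list. Single clusters are affected too. At clusters 4392 and 5511 the untreated wild-type means were lower in the snf2 tables than in the swi3 tables, so the sizes of their differences depend on the wild-type set. At DDR2 the untreated snf2 wild-type libraries exceeded the swi3 ones by more than its untreated effect of -1.70 in snf2W935R. Its difference thus depends on the wild-type set.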

How the results depend on the processing

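The alternatives with 1 cluster per gene, with only upstream clusters, without RPP1 in the ribosomal protein list and with each mutant's own wild-type libraries were chosen only after the data were seen; the others were fixed in advance. Of 103 alternatives for the results that answer a comparison, 80 left the value on its side or within 1.5 times of the original count, and 23 moved it. The 80 include 7 recomputed adjustments, which repeat the deposited one and could not move. They also include 10 median centrings, whose shifts were small. At an adjusted p under 0.01, changed clusters numbered 47 in untreated swi3E815X, 89 and 158 in snf2W935R untreated and with DTT, and 204 and 488 in snf2Q928K, which a stricter threshold lowers by construction. By the same threshold, differences between treatments fell to 0, 4 and 28 clusters in swi3E815X, snf2W935R and snf2Q928K, and calls shared by the snf2 mutants to 63 untreated and 132 with DTT. With only upstream clusters, which tests fewer, there were 1163 changed in DTT-treated wild type, 46 in untreated swi3E815X and 46 in DTT-treated swi3E815X. With 1 cluster per gene there were 50 in untreated swi3E815X and 91 in untreated snf2W935R. Under these 2 alternatives the share of higher clusters in untreated swi3E815X went from 25.5% to 38% and 37%, and in untreated snf2W935R from 34.5% to 20.9% and 20.8%. An SE for fully shared controls is smaller by construction and gave 198, 282 and 39 differences untreated (swi3E815X with snf2W935R, swi3E815X with snf2Q928K, and the snf2 pair) and 360, 452 and 67 with DTT. It applies to the snf2 pair only. For the swi3E815X pairs, which have separate wild-type libraries, it is too small and their counts under it are too high. Lists called in untreated snf2Q928K numbered 8 with log2 fold changes, and lists in DTT-treated snf2Q928K 11 at the correlation of 0.05; for the former the cause was not tested, and the latter widens every variance. Of 89 list calls, 79 held on ranks and 72 at the correlation of 0.05, and 77 of 86 held with log2 fold changes, where the textbook Swi/Snf-dependent list in untreated snf2Q928K reversed to lower (adjusted p = 0.0508, cameraPR; the cause was not tested). Not every call lost on ranks is named above. Without RPP1 the ribosomal protein list kept 6 of 6 calls. Median centring moved no count by over 1.5 times. The slopes of the DTT response with own wild-type libraries were 0.85, 0.81 and 0.64. No paired analysis was possible because the tables hold no values per library. Refits of counts with another tool, a replicate block and leaving out each replicate were planned and not run for the same reason. The errors in the tables limit what could be seen, as a simulated log2 difference of 1 between treatments was recovered at 9.92% of clusters in snf2Q928K and 1 of 4 at 95%.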

Other observations

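The 2 list tests in this part were planned, and the genes and counts below were chosen after their values were seen. Cell wall genes went both ways in DTT-treated snf2Q928K, with 2 of 19 higher and 5 lower (list adjusted p = 0.467, cameraPR). In the authors' deposited table the glucan synthase FKS1 (log2 fold change 1.21) and GAS1 (0.64) were higher, and its paralog GSC2 (-1.95), SED1 (-1.55), TIP1 (-1.33), PRM5 (-0.97) and YPS3 (-1.84) lower. Ergosterol synthesis in untreated snf2Q928K had 4 of 23 representative clusters higher, ERG2, ERG4, ERG10 and MVD1, and 2 lower, ERG1 and IDI1 (list adjusted p = 0.223, cameraPR). At SNF11, the cluster 276.5 bp upstream of the coding start was the only called Swi/Snf subunit cluster representing its gene in the snf2Q928K tables, at log2 fold changes of -5.82 and -4.52 in the authors' deposited tables, untreated and with DTT, and in wild-type cells it fell with DTT by 1.36 in the authors' deposited table.

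Changed clusters were found in each class of position. In DTT-treated snf2Q928K, 14.2% of clusters upstream of a coding start, 13.5% of those inside a coding region and 15.8% of intergenic ones changed. In untreated snf2W935R the figures were 2.69%, 0.932% and 4.81%, and in DTT-treated wild type 33.0%, 32.9% and 36.8%. Whether these shares differ was not tested. The KAR2 cluster far upstream and the TAD2 cluster (X, 380466 to 380603), on the opposite strand, were both higher in the snf2 mutants under DTT.

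The 2 libraries made without Cap-Clip, 1 untreated and 1 with DTT, are in no table used here, so the background of uncapped 5′ ends was not measured.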
